A study of Sus scrofa with 24 samples.

How the data were processed

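Bronchial epithelial cells of 1-month-old pigs, grown at an air-liquid interface, were profiled by paired-end sequencing of RNA, per the labels. The cells were preincubated for 1 h with the solvent DMSO or with 20 µM SB203580, an inhibitor of the p38 MAP kinases, and then received 100 ng/ml flagellin, the bacterial flagellum protein recognised by TLR5, or PBS, for 2 or 24 h. This gave 6 groups of 4 libraries, 24 libraries in all, and a single deposited table. PBS and flagellin below mean cultures preincubated with DMSO. There was no group given SB203580 without flagellin among the labels used here.

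The deposited table holds whole-number counts of reads per gene, not normalized. Per the submitters' processing notes, the tools were STAR 2.4.0a, featureCounts and Subread 1.4.6-p1, and the genome build named there is GRCm38, a mouse build; per the file headers and feature identifiers, the deposited counts are for pig genes. The pig assembly and the use of strand in counting are not given in the sources used here, so reads of antisense or overlapping genes cannot be told apart, and coordinates are printed as the deposited table gives them. The table had 31868 features, of which 25880 were pig genes, 5888 bacterial features, 92 ERCC spike-ins and 8 other spike-in or phiX sequences. The spike-ins had 0 counts in every library. The bacterial features had 10217 counts over all libraries in 17 of the 5888 features, 99.9% of them in features of 2889 or 1524 bases. Their highest level was 51.4 CPM in a PBS library, 49.5 in a library with flagellin alone and 17.5 with SB203580, so over both times none stood above the highest PBS library. At 24 h, replicate 3 of flagellin (16.7) and replicate 2 of SB203580 plus flagellin (17.5) lay above the PBS libraries (6.085 to 10.1). These features were left out of library sizes and tests.

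Symbols came from a table of pig gene identifiers and matched 14857 of the 25880 pig genes. A further 1483 genes without a symbol overlapped exactly 1 RefSeq gene by at least 0.5 of the spans and were named by position, which is said wherever such a gene first appears (CCL20, TNF, SAA3 and MUC5AC among them). Among 12498 genes that had a symbol by identifier and 1 RefSeq gene by position, 94.9% had the same symbol or a synonym. Position-named genes are not members of the gene lists.

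Total counts per library ranged from 26347298 to 36269083 (median 32494461), and 15878 to 16524 genes had a count. A floor of 3 counts, the most that a count of 0 allows, lay between 0.0827 and 0.114 CPM; floors and counting intervals cover counting error only. No 2 libraries of a group were duplicates, as the chi-square per gene was 10.8 to 413 over the 36 pairs. The labels do not say whether replicates were separate animals or cultures. Genes of the Y chromosome had counts in all libraries of replicates 1 and 2 and almost none in replicates 3 and 4. These 2 sets therefore did not come from the same animals, and each group of 4 holds 2 libraries of each set. The p-values measure the spread between these libraries, which may be partly technical, and the 4 may not be 4 independent animals. A fit without a block counts the difference between the 2 sets as spread, though each group holds both equally. This can widen its standard errors, so a count of 0 there does not show that no gene changed. For flagellin at 2 h it called 46 genes. A term for the set at each time, chosen after the data were seen, called 318.

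Counts were scaled with TMM factors (0.836 to 1.07) and genes were kept by the filterByExpr rule of edgeR, which left 14172 genes, 11856 of them with a symbol. The test was edgeR's quasi-likelihood F test with robust settings (edgeR 4.0.16, R 4.3.3), on all 24 libraries with 1 term per group and no block, which left 18 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and an adjusted p under 0.05 counted as a call. Counts at an unadjusted p under 0.05 are not calls. Where no gene changes, a share of about 0.05 of the genes tested reaches it by chance. Levels are CPM (counts scaled by TMM-adjusted library size; floors and bacterial levels use the plain total) with the SD over n = 4 libraries. Fold changes are log2 values, and a standard error (SE) is the absolute log2 fold change divided by the square root of F. All p-values are two-sided and come from edgeR unless limma or DESeq2 is named.

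The comparisons were flagellin against PBS, SB203580 plus flagellin against flagellin, and SB203580 plus flagellin against PBS at each time, 24 h against 2 h in PBS, and the interactions of flagellin and of SB203580 with time. Gene lists of 24 pathways and 11 cell types were fixed, of which 34 had enough tested members; 558 of their 767 symbols matched a tested gene and 6 genes were in more than 1 list. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry. A list is said to have changed only where both forms of camera gave an adjusted p under 0.05. Members past the threshold are counted over all genes tested and adjusted over the list alone.

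Genes were named by a fixed rule: the 5 largest rises and 5 largest falls with a symbol, a mean log2 CPM of at least 1 and no overlap between the 4 libraries of each group; up to 3 members with the smallest adjusted p of each list with called members, up to 10 lists, and of any list past camera; and 12 genes given in every comparison (TLR5, CXCL8, CCL20, IL6, TNF, CSF3, PTGS2, LCN2, SAA3, DUSP1, ZFP36 and MUC5AC). For interactions the 5 largest in each direction were named. In the fit with the replicate number as a block, the rule for list members was applied but not that for largest changes. In the fit with a term for the set at each time both were applied. There the condition of no overlap was replaced by 1 direction in all 4 pairs of libraries with the same number. Groups, comparisons, tests, gene lists, the rule for the fit without a block and the first group of other settings were fixed before the data were examined.

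The replicate numbers of the labels are shared by all groups, and whether they pair the libraries was checked from the deviations of each library from its group mean. All 60 pairs of libraries with the same number had a correlation across genes over 0.1 (lowest 0.211, median 0.600). Libraries with another number of the same set, 1 with 2 or 3 with 4, had a median of 0.603 and a lowest value of 0.0664, and those of the other set a highest value of -0.324. All 24 libraries correlated best with a library of their own set and 13 with one of their own number. The correlations thus told the sets apart, but not the numbers within a set. The rule fixed for pairing, a correlation over 0.1, was met all the same. Results with the replicate number as a block (15 residual degrees of freedom) are therefore given where they change a call or move a count by over 1.5 times. Directions given per replicate below compare libraries of the same number. For genes named as largest rises or falls, 1 direction in all 4 replicates follows from the rule that picked them. It is not added evidence for those genes.

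Other settings chosen beforehand were RLE scaling, no count filter, DESeq2 1.42.0, a fit of the groups compared alone, the replicate block and leaving out each library in turn. Added after the data were seen were a term for the set of replicates (1 and 2 against 3 and 4), a term for that set at each time, each set alone, and fits without 5 libraries low in secretory cell markers, alone or with a block. Overlaps of comparisons that share libraries were set beside 20 simulated data sets without effects, independent lists and a split of the shared libraries. The fits were tested on simulated counts with 200 genes changed: without a block, 67% of 2-fold and 90% of 4-fold changes were recovered for flagellin at 2 h with 0 false calls among 13840 unchanged genes. For flagellin at 24 h the shares were 67% and 93%, for SB203580 at 2 h 67% and 90%, and for SB203580 at 24 h 60% and 91%; with the replicate block at 24 h they were 88% and 98% for flagellin. False calls for SB203580 numbered 2 of 13834 unchanged genes at 2 h and 0 of 13837 at 24 h without a block, 4 and 5 with the replicate block, and 7 and 11 with the term for the set at each time; for flagellin they were 0 and 0, 0 and 5, and 3 and 8. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.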

Results

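RNA was measured in 24 cultures of pig bronchial epithelium, the ciliated and secretory lining of the large airways, grown with their upper surface in air. The 6 groups of 4 libraries were PBS, flagellin, and SB203580 plus flagellin, each at 2 h and at 24 h. Flagellin, the ligand of the receptor TLR5, was given at 100 ng/ml, and SB203580, a small-molecule inhibitor of p38 kinase, at 20 µM for 1 h beforehand. Libraries held 26347298 to 36269083 counts, with 15878 to 16524 genes detected.

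Libraries numbered 1 or 2 and libraries numbered 3 or 4 formed 2 sets that differed in every group. Markers of squamous epithelium, the flat keratinising form that airway cells can take, had a mean log2 CPM of 5.98 ± 0.84 (SD, n = 12) in replicates 1 and 2 and 3.70 ± 0.49 (n = 12) in replicates 3 and 4, with no overlap between libraries. Club and secretory cell markers were at 7.47 ± 0.52 against 6.04 ± 0.36, mucins and goblet cell genes at 5.01 ± 0.51 against 3.84 ± 0.17, and proliferation genes at 4.08 ± 0.32 against 2.86 ± 0.41. Fibroblast and smooth muscle markers lay the other way, at 1.36 ± 0.24 against 1.86 ± 0.08, as did endothelial markers, at 2.74 ± 0.30 against 3.24 ± 0.26. EIF1AY and KDM5D, genes of the Y chromosome, were at 15.4 to 32.8 and 3.49 to 5.76 CPM in the 12 libraries of replicates 1 and 2, and at 0 to 0.0297 and 0 CPM in the other 12. The share of mitochondrial counts was 4.29% to 6.16% in the first set and 3.03% to 4.00% in the second.

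The difference between the sets covered 7370 of 14172 genes at 2 h (3707 higher and 3663 lower in replicates 3 and 4) and 9152 at 24 h (4484 and 4668). Averaged over the 6 groups, replicate 2 differed from replicate 1 in 1 gene (1062 at an unadjusted p under 0.05) by edgeR. Replicate 4 differed from replicate 3 in 0 genes by edgeR (859 at an unadjusted p under 0.05), and no other tool was run on these differences. Such an average does not show differences within single groups. The chi-square per gene between replicates 1 and 2 was 15.15 in PBS at 24 h but 195 in flagellin at 24 h, where replicates 1 and 3 gave 205. The first principal component, 47.6% of the variance, placed replicates 1 and 2 between -62.2 and -35.6 and replicates 3 and 4 between 30.0 and 59.7, and the second, 14.9%, placed 2 h between -34.0 and -17.0 and 24 h between 14.7 and 35.7. Within the first set 5 libraries had club and secretory cell markers at 6.72 to 7.25, below the other 7 at 7.79 to 8.11. These were replicate 2 of PBS at 2 h, replicate 2 of flagellin at 24 h, replicate 1 of SB203580 plus flagellin at 2 h, and replicates 1 and 2 of SB203580 plus flagellin at 24 h. Their ciliated cell markers were at 0.30 to 1.14 log2 CPM, where the other 7 lay between 1.71 and 2.45. Low here and below means low for that set. In replicates 3 and 4 the club and secretory cell markers lay between 5.56 and 6.84 and the ciliated cell markers between 0.31 and 1.98.

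**Figure D1:**
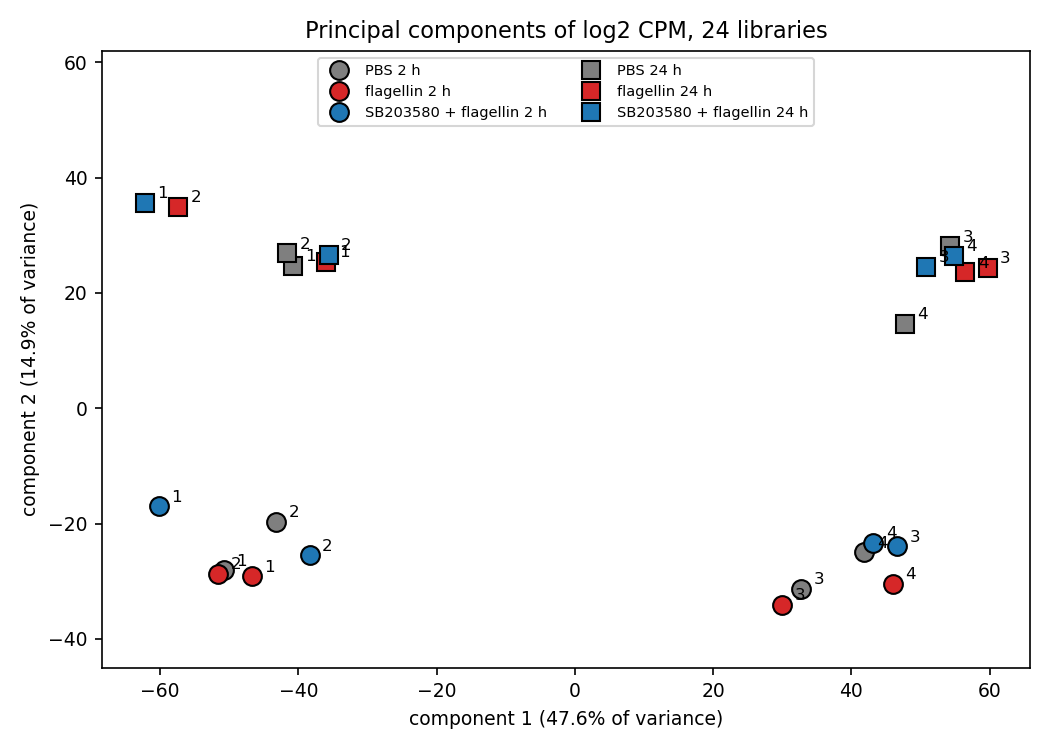
Scores of the 24 libraries on the first (47.6% of the variance) and second (14.9%) principal components of log2 CPM, with the replicate number beside each point; circles are 2 h, squares 24 h, grey PBS, red flagellin and blue SB203580 plus flagellin. Replicates 1 and 2 lie at -62.2 to -35.6 on the first component and replicates 3 and 4 at 30.0 to 59.7.

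Flagellin against PBS at 2 h asked which genes the epithelium switches on soon after contact with this bacterial protein. CXCL8, a chemokine that attracts neutrophils, rose from 33.4 ± 18.4 to 655 ± 67.8 CPM (SD, n = 4 each), a log2 fold change of 4.29 (SE 0.746, adjusted p = 0.00943), and was higher in 4 of 4 replicates. CD83, a surface glycoprotein of activated immune and epithelial cells, rose by 4.16 (SE 0.308, adjusted p = 1.63e-07), from 1.89 ± 0.513 to 33.8 ± 5.72 CPM. The transcription factor IRF1 rose by 3.34 (SE 0.335, adjusted p = 7.21e-06) and TNFAIP3, the ubiquitin-editing enzyme A20 that restrains NF-kB, by 3.25 (SE 0.384, adjusted p = 6.96e-05), from 132 ± 22.8 to 1258 ± 248 CPM. The alarmin IL1A, an early signal of the interleukin 1 family, rose by 2.34, from 63.3 ± 24.3 to 321 ± 23.2 CPM. Each of these genes was higher in 4 of 4 replicates.

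In the coordinates of the deposited counts, CXCL8 (ENSSSCG00000008953) lies on chromosome 8 at 69932644 to 69935861, CD83 (ENSSSCG00000021576) on chromosome 7 at 10359211 to 10387002, and IRF1 (ENSSSCG00000014277) on chromosome 2 at 134776124 to 134783819. TNFAIP3 (ENSSSCG00000004154) lies on chromosome 1 at 26473935 to 26489776 and IL1A (ENSSSCG00000008090) on chromosome 3 at 43718427 to 43731120. Counts are over the exons of each gene.

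Among the NF-kB feedback genes, which are induced by NF-kB and limit it, 9 of 22 tested members rose over all genes tested and 15 adjusted over the list alone, with none lowered in either count. NFKBIE, an inhibitor that holds NF-kB in the cytoplasm, rose by 1.88 (adjusted p = 2.65e-07), NFKBID by 2.88 (adjusted p = 7.21e-06) and BIRC3, an inhibitor of apoptosis, by 1.68 (adjusted p = 7.97e-05). The list had a median log2 fold change of 1.11 and rose by camera (adjusted p = 6.54e-68, and adjusted p = 3.44e-05 with an estimated correlation). Of the 16 cytokines and colony-stimulating factors tested, 3 rose over all genes and 6 adjusted over the list alone, and the list rose (adjusted p = 0.00676 with an estimated correlation). IL1A, the macrophage growth factor CSF1 at 2.44 (adjusted p = 0.00986) and the interleukin 10 family member IL20 at 4.91 (adjusted p = 0.0415) were the 3; IL20 was near the detection floor in PBS, at 0.128 ± 0.147 CPM. The TLR5 signalling components rose as a list (adjusted p = 0.0478 with an estimated correlation) although 0 of 22 members passed over all genes by edgeR and 3 passed adjusted over the list alone. This call was lost without any 1 of replicates 2, 3 and 4 of flagellin (adjusted p = 0.0615, 0.0879 and 0.13 with an estimated correlation) or replicates 1, 2 and 4 of PBS (0.0756, 0.158 and 0.0845). It was also lost with RLE scaling (0.0578), no count filter (0.0729), the groups compared alone (0.0786) and the term for the set at each time (0.105). The call of the cytokines was lost without replicate 4 of PBS (0.0636) and with no count filter (0.0798). Chemokines had 1 of 13 members called, CXCL8, and an adjusted p = 0.232 with an estimated correlation; with the replicate number as a block 4 rose and this p was 0.00669.

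Single members of other lists also rose at 2 h. PGLYRP2, an enzyme that cleaves bacterial peptidoglycan, rose by 2.47 (adjusted p = 0.0195), ZC3H12A, an endonuclease that degrades cytokine mRNA, by 2.28 (adjusted p = 0.0301), and PLAUR, the urokinase receptor, by 1.57 (adjusted p = 0.0144). PMAIP1, a pro-apoptotic BH3-only protein, rose by 1.12 (adjusted p = 0.00215), the mitochondrial superoxide dismutase SOD2 by 0.87 (adjusted p = 0.0214), and PFKFB3, a driver of glycolysis, by 0.78 (adjusted p = 0.0369). TNFAIP2, a gene induced by TNF, rose by 2.98 (adjusted p = 0.00986). The falls were small: CCDC126 fell by 0.64, TBL1XR1 by 0.56, FAM199X by 0.39 and FAM8A1 by 0.38, each lower in 4 of 4 replicates (adjusted p = 0.0169, 0.0186, 0.0301 and 0.0172). The receptor TLR5 itself was at 0.931 ± 0.182 CPM with flagellin and 0.785 ± 0.275 with PBS, a log2 difference of 0.25 that did not pass. Also not past the threshold were PTGS2, the inducible cyclooxygenase, at 1.05 (SE 0.549), IL6 at 1.03, CSF3 at 1.97, LCN2 at 0.31, DUSP1 at 0.07, ZFP36 at 0.97, SAA3 at 1.84 and MUC5AC at 0.17; SAA3 and MUC5AC were named by position.

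At 2 h 42 genes rose and 4 fell of 14172 tested, 30 of the 46 by at least 2-fold. At an unadjusted p under 0.05 there were 721 (5.09%). With the replicate number as a block 114 rose and 37 fell, and all 46 were among them. Genes past the threshold with that block and not without a block included CXCL2 at 4.70 (adjusted p = 1.03e-05), CCL20 at 5.30 (adjusted p = 0.00137) and TNF at 4.96 (adjusted p = 0.000993), the last 2 named by position. Others were RND1, LIF, VCAM1, AMCF-II, CCL2, MAP3K8, TLR2, PLAU, IER3, ZFP36 and GDF15; GCLM and ZMAT3 fell there. CXCL8, CXCL2 and AMCF-II are related genes that lie close together, so their counts may share reads. There were 20 genes in replicates 1 and 2 alone and 198 in replicates 3 and 4 alone; DESeq2 gave 84 raised and 18 lowered. The count fell to 22 without replicate 2 of PBS, 15 without replicate 3 of PBS, 20 without replicate 3 of flagellin and 29 without replicate 4 of flagellin.

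**Figure D2:**
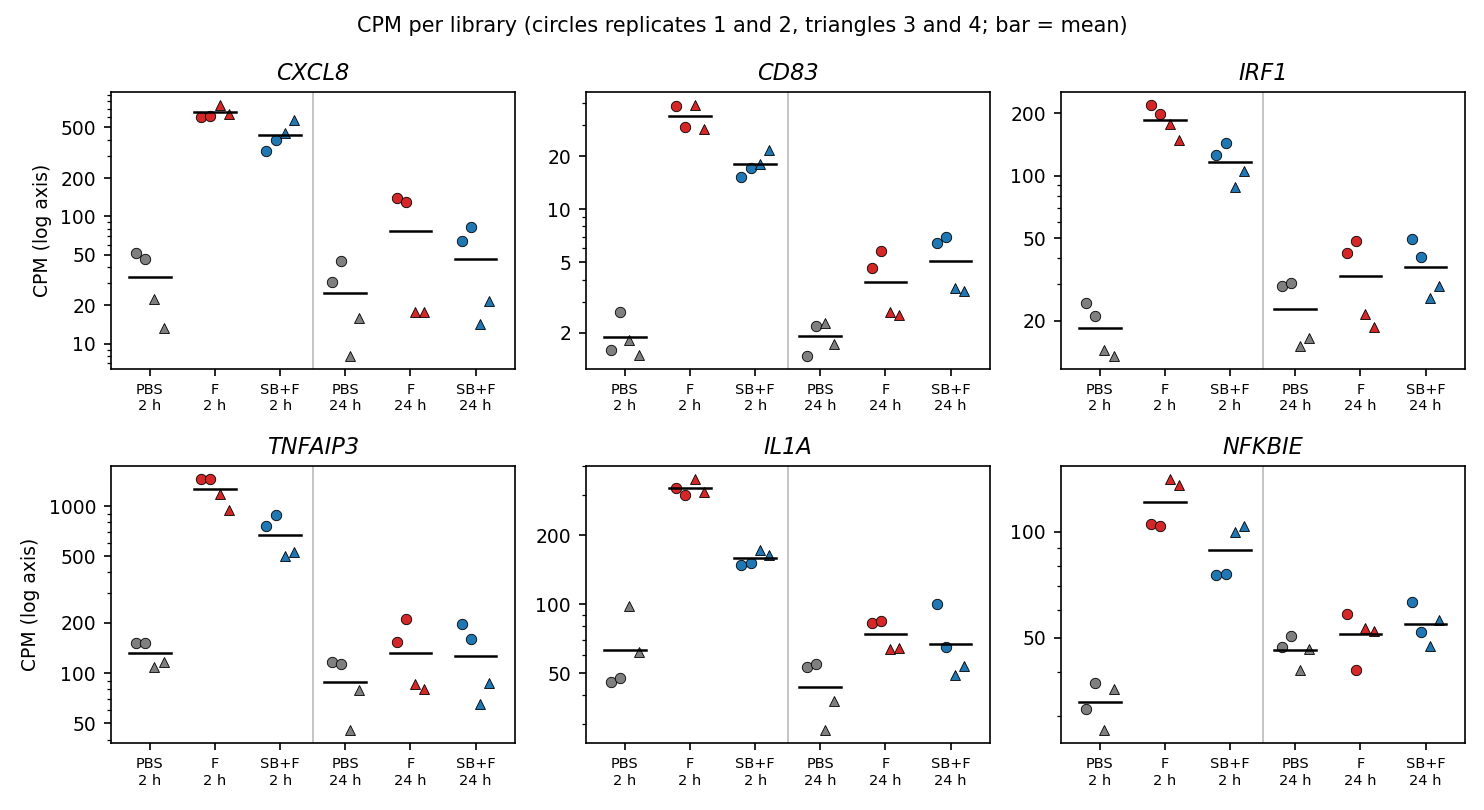
CPM of CXCL8, CD83, IRF1, TNFAIP3, IL1A and NFKBIE in each library of the 6 groups on a log axis; circles are replicates 1 and 2, triangles replicates 3 and 4, bars the mean, and values below the floor of 3 counts (at most 0.114 CPM) are drawn at it. TNFAIP3 has a mean of 1258 CPM with flagellin at 2 h and 132 with PBS.

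At 24 h the same comparison asked what remained of the response. CXCL8 was at 76.3 ± 67.8 CPM with flagellin and 24.8 ± 16.3 with PBS (SD, n = 4), a log2 difference of 1.62 (SE 0.67) that did not pass the threshold (adjusted p = 1.00) though it was higher in 4 of 4 replicates. The chemokine CCL20 differed by 1.96, IL6 by 2.15 and PTGS2 by 0.91. The value of IL6 is uncertain, as its PBS level was near the detection floor. PTGS2 was at 284 CPM in replicate 2 of flagellin and 73.6 to 77.9 in the others, and without that library its difference was 0.16. The gel-forming mucin MUC5AC differed by -1.23 and the iron-binding antimicrobial protein LCN2 by -1.12, each lower in 4 of 4 replicates and neither past the threshold. In replicates 1, 2, 3 and 4 MUC5AC was at 1310, 264, 333 and 219 CPM with flagellin and 2307, 1733, 391 and 544 with PBS. LCN2 was at 146, 23.9, 18.9 and 13.7 against 186, 207, 19.5 and 25.5. DUSP1 differed by 0.13, ZFP36 by 0.33, TNF by 0.25, SAA3 by 0.05, CSF3 by -0.35 and TLR5 by -0.38.

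By edgeR 0 genes passed at 24 h, with 112 (0.79% of those tested) at an unadjusted p under 0.05. The replicate block gave 0 with 390 (2.75%), a term for the set at each time 0 with 535 (3.78%), and DESeq2 1 gene with 189 (0.97%). All these shares are under 0.05, so the counts are no sign of further changed genes. By camera at the preset correlation 14 of 34 lists passed, but 0 passed with an estimated correlation: the NF-kB feedback genes had a median of 0.22 (adjusted p = 0.256 with an estimated correlation), the cytokines 0.61 (0.256), and the ciliated cell markers -0.63 (0.256). With the replicate block the cytokines passed (adjusted p = 0.00186 with an estimated correlation). One of the 4 flagellin libraries at 24 h, replicate 2, was among those low in club, secretory and ciliated cell markers. Each set of replicates alone also gave 0 genes by edgeR, with 501 and 463 at an unadjusted p under 0.05.

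SB203580 plus flagellin against flagellin at 2 h asked how inhibition of p38 alters the response. CBX8, a subunit of the Polycomb repressive complex PRC1, rose from 3.94 ± 0.397 to 10.7 ± 1.02 CPM (SD, n = 4), by 1.44 (SE 0.185, adjusted p = 0.00223), and was higher in 4 of 4 replicates. It was the only gene called by edgeR (ENSSSCG00000034146, chromosome 12, 2562335 to 2567624), and 321 genes (2.27% of those tested) had an unadjusted p under 0.05. With the replicate number as a block 4 genes fell as well, among them ZFP36, the mRNA-destabilising protein tristetraprolin, by 1.12 (adjusted p = 0.0379), and OTUD1, a deubiquitinase, by 1.02 (adjusted p = 0.0254). OTUD1 lies outside the rule for named genes and was picked after its value was seen.

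A fit with a term for the set of replicates at each time, chosen after the data were seen, called 37 genes lowered and 16 raised by SB203580 at 2 h. In it the immediate early transcription factors FOS fell by 1.05 (SE 0.192, adjusted p = 0.017), JUNB by 0.91 (adjusted p = 0.0328) and NR4A3 by 1.66 (adjusted p = 0.0328). The alarmin IL1A fell by 1.01 (adjusted p = 0.00488), from 321 ± 23.2 to 160 ± 11.2 CPM. TNFAIP3 fell by 0.93 (adjusted p = 0.00488), from 1258 ± 248 to 669 ± 184 CPM, and IRF1 by 0.69 (adjusted p = 0.00488). The urokinase PLAU fell by 0.98 and its receptor PLAUR by 0.95. So did the phosphatase DUSP1, which switches off p38 and JNK, by 0.73 (adjusted p = 0.02), ZFP36L1, a relative of ZFP36, by 0.65, and the phosphatase subunit PPP1R15A by 0.73. SNAI1, a repressor of E-cadherin, fell by 1.44, RND1 by 1.23, and BIRC3 by 0.48. TFAP4, a helix-loop-helix transcription factor, rose by 1.17 (adjusted p = 0.013), ZNF180 by 0.95, MAP10 by 0.93 and CLSTN3 by 0.93. All of these moved one way in 4 of 4 replicates, which was a condition for those named as largest changes. None but CBX8 passed in the fit without a block, where for example IL1A was at -1.01 (adjusted p = 0.494) and DUSP1 at -0.74 (adjusted p = 0.212).

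Some inflammatory genes had lower levels that did not pass. With the term for the set, PTGS2 differed by -1.70 (adjusted p = 0.0502), CXCL8 by -0.58 (adjusted p = 0.81) and CCL20 by -1.12 (adjusted p = 0.499), each lower in 4 of 4 replicates. In the fit without it TNF differed by -0.30, CSF3 by -0.84, IL6 by -0.49, LCN2 by -0.35, MUC5AC by -0.47, SAA3 by -0.09 and TLR5 by -0.07. Of 34 lists 0 passed with an estimated correlation, including the NF-kB feedback genes (median -0.31, adjusted p = 0.158 with an estimated correlation) and the immediate early genes (median -0.38, 0.183). With the term for the set these 2 lists and the cytokines each had an adjusted p = 0.0374 with an estimated correlation. Ciliated cell markers had a median of -0.84 in the same comparison (adjusted p = 0.318 with an estimated correlation), and 1 of the 4 SB203580 libraries was among those low in secretory markers for replicates 1 and 2. Replicates 1 and 2 alone gave 0 genes (316 at an unadjusted p under 0.05) and replicates 3 and 4 alone 93 by edgeR, DESeq2 gave 13, and without replicate 3 of SB203580 plus flagellin the count was 2.

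**Figure D3:**
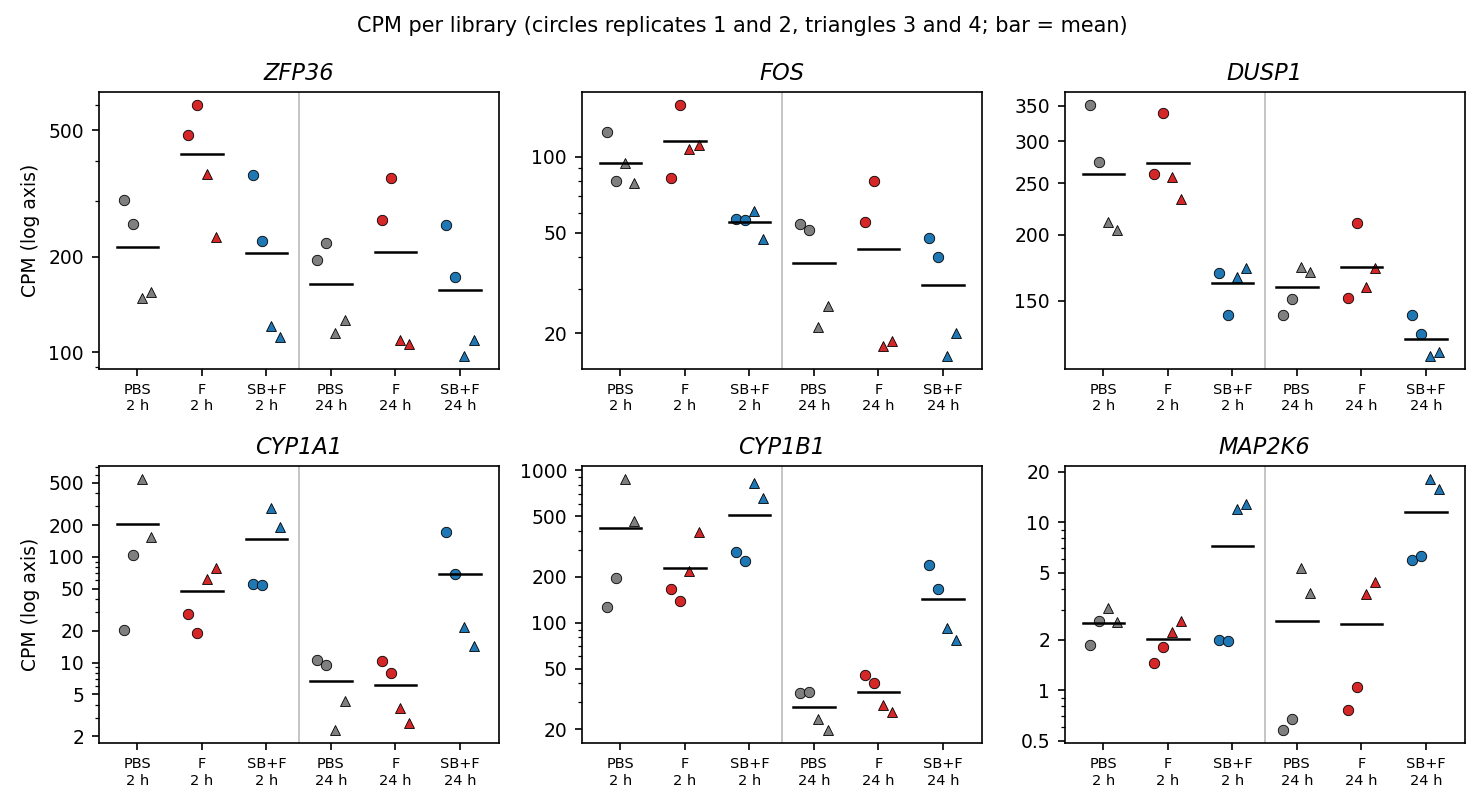
CPM of ZFP36, FOS, DUSP1, CYP1A1, CYP1B1 and MAP2K6 in each library of the 6 groups on a log axis; circles are replicates 1 and 2, triangles replicates 3 and 4, and bars the mean. At 24 h CYP1B1 has a mean of 143 CPM with SB203580 plus flagellin, 35.1 with flagellin and 28.2 with PBS.

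SB203580 plus flagellin against PBS at 2 h compares groups that differ in both the inhibitor and flagellin; cultures with SB203580 alone were not analysed here. CXCL8 rose by 3.71 (SE 0.726, adjusted p = 0.0323), to 436 ± 102 CPM (SD, n = 4) from 33.4 ± 18.4 with PBS, CD83 by 3.25 (adjusted p = 7.26e-06) and TNFAIP2 by 2.78 (adjusted p = 0.0246). CSF1 rose by 2.74 (adjusted p = 0.00688), IRF1 by 2.66 (adjusted p = 0.00028) and TNFAIP3 by 2.34 (adjusted p = 0.00688). KLHL38, a Kelch family protein, rose by 2.88 (adjusted p = 0.0246), from 0.819 ± 0.26 to 6.05 ± 0.786 CPM. Each was higher in 4 of 4 replicates.

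The NF-kB feedback genes rose as a list (adjusted p = 0.00171 with an estimated correlation), with 5 of 22 members raised over all genes and 12 adjusted over the list alone, among them NFKBID at 2.29, NFKBIE at 1.42 and BIRC3 at 1.21. The cytokines rose as well (adjusted p = 0.041 with an estimated correlation), with 2 of 16 members raised, CSF1 and IL1A at 1.33 (adjusted p = 0.0206), and 5 adjusted over the list alone. This call was lost without replicate 3 or 4 of PBS (adjusted p = 0.0874 and 0.222 with an estimated correlation) or replicate 1 or 2 of SB203580 plus flagellin (0.172 and 0.191), and with no count filter (0.546). Genes lowered against PBS were TMEM263 by 0.74, SERTAD3, a cell cycle regulator, by 0.58, SLC30A1, a zinc exporter, by 0.55, TOB1, an antiproliferative protein, by 0.53, and SOCS6, a suppressor of cytokine signalling, by 0.48. Of the genes given in every comparison, IL6 differed by 0.54, CCL20 by 3.14, TNF by 3.94, SAA3 by 1.75, CSF3 by 1.13, TLR5 by 0.17, LCN2 by -0.05, ZFP36 by -0.07, MUC5AC by -0.30, PTGS2 by -0.66 and DUSP1 by -0.68, none past the threshold. In all 19 genes rose and 7 fell, 14 of the 26 by at least 2-fold, with 673 at an unadjusted p under 0.05.

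With the replicate block 72 rose and 42 fell, all 26 among them, and CCL20 (4.17, adjusted p = 0.0123), TNF (3.94, adjusted p = 0.0119) and CXCL2 (3.53, adjusted p = 0.000354) rose and DUSP1 fell by 0.66 (adjusted p = 0.0439). The chemokines then passed as a list (adjusted p = 0.019 with an estimated correlation, against 0.455 without the block). The first set alone gave 14 genes and the second alone 183; DESeq2 gave 49 raised and 32 lowered. The count was 13, 10 and 11 without replicates 1, 2 and 3 of PBS, and 16 and 13 without replicates 3 and 4 of SB203580 plus flagellin.

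At 24 h, SB203580 plus flagellin against flagellin gave 0 genes by edgeR, 0 with the replicate block and 1 by DESeq2. At an unadjusted p under 0.05 there were 405 (2.86% of those tested), 944 (6.66%) and 530 (2.72%). CYP1A1, a monooxygenase induced by ligands of the aryl hydrocarbon receptor (AhR), was at 68.8 ± 71.9 CPM with SB203580 and 6.18 ± 3.59 without (SD, n = 4). CYP1B1, its relative, was at 143 ± 74.5 and 35.1 ± 9.21, and MAP2K6, the kinase MKK6 that activates p38, at 11.5 ± 6.33 and 2.49 ± 1.86. In the fit with a term for the set at each time, where 10 genes rose and 3 fell, CYP1B1 rose by 1.95 (SE 0.251, adjusted p = 0.00408), MAP2K6 by 2.42 (SE 0.369, adjusted p = 0.0173) and CYP1A1 by 3.17 (SE 0.517, adjusted p = 0.0289), each higher in 4 of 4 replicates. Without that term their adjusted p was 1.00. NRAP rose by 0.94 and NXPE3 by 0.63 there, PCDH9, a protocadherin, fell by 0.80, and EHD2, a membrane-remodelling ATPase of caveolae, by 0.58.

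The other genes given in every comparison were CXCL8 at -0.73, PTGS2 at -0.84 (-0.11 without replicate 2 of flagellin), DUSP1 at -0.45, ZFP36 at -0.39, CCL20 at -0.17, MUC5AC at -0.03, SAA3 at 0.00494, LCN2 at 0.11, CSF3 at 0.20, TLR5 at 0.32, IL6 at 0.35 and TNF at 0.56, none past the threshold. By camera 6 of 34 lists passed at the preset correlation and 0 with an estimated one; the interferon-stimulated genes had a median of 0.19 (adjusted p = 0.927 with an estimated correlation). Without the 5 libraries low in secretory markers the term for the set gave 1 gene, and CYP1B1 was at 1.62 (SE 0.364, adjusted p = 0.176); 2 of the 4 SB203580 libraries and 1 flagellin library are among these 5. By set, replicates 1 and 2 gave 2 genes and replicates 3 and 4 gave 1.

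Against PBS at 24 h, SB203580 plus flagellin raised EXT1, a glycosyltransferase of heparan sulfate synthesis, from 39.4 ± 3.1 to 68.1 ± 11.4 CPM (SD, n = 4), by 0.79 (SE 0.12, adjusted p = 0.0266), higher in 4 of 4 replicates (ENSSSCG00000006009, chromosome 4, 20645038 to 20935759). With the replicate number as a block 9 genes rose, among them MAP2K6 by 2.41 (adjusted p = 0.0349), CEACAM19, an adhesion molecule, by 1.53 (adjusted p = 0.0484) and ERAP1, a peptidase that trims antigens, by 0.52 (adjusted p = 0.0372). With a term for the set at each time 59 rose and 6 fell. In it CYP1A1 rose by 3.09, CYP1B1 by 2.27, the adhesion molecule VCAM1 by 2.32, CD83 by 1.32 and S100A12, an antimicrobial calcium-binding protein, by 1.12. CSF1 rose by 1.09, the serine synthesis enzyme PHGDH by 1.02, the immunoproteasome subunit PSMB10 by 0.85, IRF1 by 0.70 and SOD2 by 0.62. LGALS3, the lectin galectin 3, fell by 0.53 (adjusted p = 0.0254), from 1753 ± 129 to 1213 ± 130 CPM.

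Not past the threshold in that comparison were CXCL8 at 0.88, CCL20 at 1.79, IL6 at 2.49, TNF at 0.81, PTGS2 at 0.07, SAA3 at 0.06, TLR5 at -0.06, ZFP36 at -0.06, CSF3 at -0.15, DUSP1 at -0.32, LCN2 at -1.01 and MUC5AC at -1.26. IL6 was near the detection floor in PBS. Of 34 lists 13 passed camera at the preset correlation and 0 with an estimated one, where the ciliated cell markers (median -1.17) and the cytokines (median 0.74) had an adjusted p = 0.191; with the replicate block the cytokines had 0.00261. There were 603 genes at an unadjusted p under 0.05, and DESeq2 gave 8 raised and 2 lowered. Without the 5 libraries low in secretory markers the count was 0 by edgeR, with 20 raised and 2 lowered where a term for the set at each time was added, and each set of replicates alone gave 2. EXT1 was no longer called, with a count of 0, without any 1 of replicates 1, 2, 3 and 4 of PBS or replicates 1 and 2 of SB203580 plus flagellin, and the count was 2 without replicate 4 of the latter.

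The comparisons of flagellin with PBS and of SB203580 with flagellin share the flagellin libraries, and their overlap asks which induced genes the inhibitor lowers. Of the 42 genes raised by flagellin at 2 h, 39 had a lower fitted level with SB203580, with a median log2 fold change of -0.47; their median was 1.47 for flagellin against PBS and 0.95 for SB203580 plus flagellin against PBS. Called both raised and lowered were 0 genes by edgeR (4 by DESeq2), 2 with the replicate block, ZFP36 and OTUD1, and 20 with a term for the set at each time, where independent lists would share 0.0322 and 0.475. Named among the 20 were TNFAIP3, IRF1, CD83, IL1A, BIRC3, PLAU, PLAUR, ITPKC, JUNB, PPP1R15A, ZFP36, ZNF263, KDM6B, SNAI1 and RND1. With the flagellin libraries split between both comparisons the median over the genes called raised in each split, 10 to 17 genes, lay between -0.63 and -0.50. With the term for the set this median, over 86 to 119 genes, lay between -0.47 and -0.31, and 0 to 7 genes were called both ways.

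**Figure D4:**
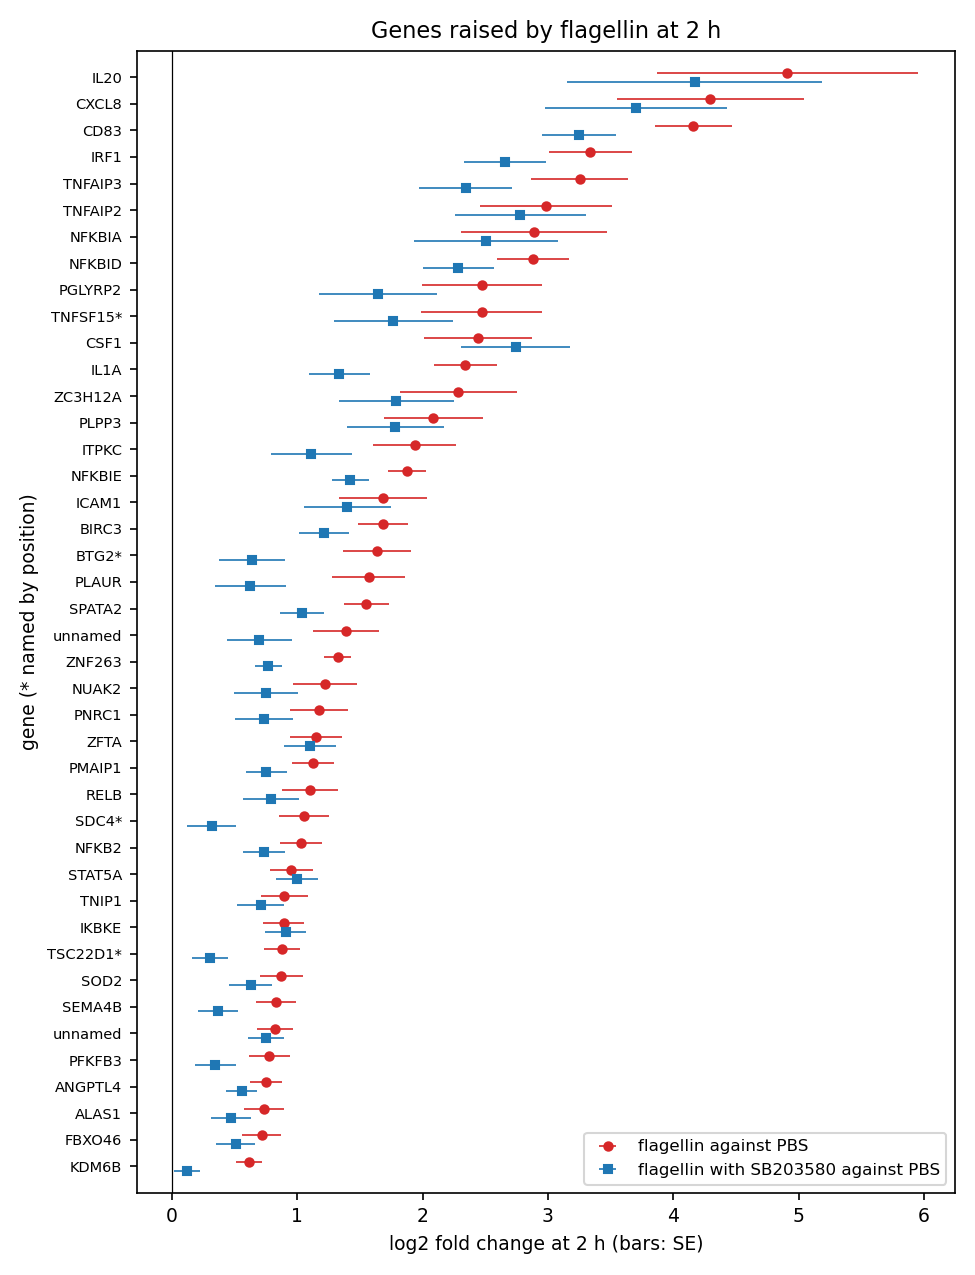
Log2 fold changes with standard errors at 2 h of the 42 genes raised by flagellin, for flagellin against PBS (red circles) and SB203580 plus flagellin against PBS (blue squares); an asterisk marks genes named by position. The median is 1.47 for flagellin and 0.95 with SB203580.

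Across all genes the fold changes of the 2 comparisons at 2 h had a Pearson correlation of -0.475 and a covariance of -0.0475. Simulated groups without effects, all libraries simulated and the flagellin ones shared, gave means of -0.498 and -0.0413. Genes are not independent replicates. With the real flagellin libraries split the correlation at 2 h was -0.211 to -0.154. At 24 h the correlation was -0.177 and the simulated ones -0.532 to -0.478, so the simulation is not a close reference there. At 24 h 0 genes were called raised and lowered by edgeR, DESeq2, the replicate block or the term for the set, and 0 genes were raised by flagellin by edgeR there (112 at an unadjusted p under 0.05 in either direction).

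Time in culture was compared in PBS, 24 h against 2 h. SLC16A3, the lactate exporter MCT4, rose by 3.55 (SE 0.365, adjusted p = 1.60e-05), from 4.83 ± 1.58 to 56.8 ± 7.05 CPM (SD, n = 4). NDRG1, a gene induced in hypoxia, rose by 2.58 (adjusted p = 4.81e-05), from 187 ± 30.6 to 1117 ± 194 CPM, and ALDOA, aldolase A, by 1.16 (adjusted p = 6.21e-05). The nuclear receptor NR4A3 fell by 4.23 and its relative NR4A1 by 2.06 (adjusted p = 0.00147), FOSB by 3.04 (adjusted p = 0.0138) and ATF3 by 1.29 (adjusted p = 5.51e-05). CYP1A1, a target of AhR, fell by 4.96 (SE 1.00, adjusted p = 0.0038) and CYP1B1 by 3.88 (SE 0.577, adjusted p = 0.000289), from 416 ± 341 to 28.2 ± 7.88 CPM. TLR5, the flagellin receptor, rose by 1.29 (adjusted p = 0.0393), from 0.785 ± 0.275 to 1.93 ± 0.574 CPM. All moved one way in 4 of 4 replicates.

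Of 18 tested genes of glycolysis and hypoxia 11 rose and none fell over all genes, and 13 rose and 1 fell adjusted over the list alone; the median was 0.75 (camera adjusted p = 2.5e-14, and adjusted p = 0.0711 with an estimated correlation). PDK1, which diverts pyruvate from the mitochondria, rose by 1.03, lactate dehydrogenase LDHA by 0.91 and PGK1 by 0.77. Of 25 immediate early genes 6 fell (7 adjusted over the list alone; adjusted p = 0.582 with an estimated correlation). Of 7 AhR targets 3 fell (4; 0.255), CYP1A1, CYP1B1 and TIPARP by 1.16. Of 18 genes of the NRF2 oxidant response 3 fell (4; 0.582), the cystine carrier SLC7A11 by 1.19, OSGIN1 by 0.86 and SOD2 by 0.63. Of 23 cholesterol synthesis genes 2 fell (3; 0.792), HSD17B7 by 0.86 and CYP51A1 by 0.72. Of 20 genes of ion and fluid transport 4 fell (0.255), among them the aquaporin AQP3 by 1.32, from 1555 ± 299 to 625 ± 196 CPM, and the chloride carrier SLC12A2 by 0.74. Of 26 genes of the p38 and stress kinase pathway 4 fell, among them DUSP1 by 0.71, GADD45B by 0.64 and MAPK8 by 0.64.

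Among the largest rises were the receptor tyrosine kinase KIT at 4.06 (adjusted p = 0.00689), NXPH4 at 3.29, the hormone STC1 at 3.21 and the fructose carrier SLC2A5 at 3.17, and among the largest falls the deiodinase DIO2 at -4.18 (adjusted p = 0.00252). Single markers of other cell types passed: of 7 macrophage and myeloid markers CD68 rose by 1.37 (adjusted p = 0.00232), of 13 of fibroblasts and smooth muscle MYH11 by 1.01, and of 5 of lymphocytes CD79A by 0.84. Of 5 endothelial markers TIE1 rose (adjusted p = 0.00526), and of 8 of glands and alveoli SFTPD, a surfactant protein, fell by 1.52. None of these lists passed (adjusted p = 0.591, 0.792, 0.591, 0.255 and 0.792 with an estimated correlation). TLR1 rose by 0.99 and TLR4 fell by 0.59. The mucin glycosyltransferase GALNT5 fell by 1.54, PTX3, a soluble pattern receptor, by 3.43, IL6 by 2.65 (adjusted p = 0.0483, at most 0.217 ± 0.136 CPM), SERPINB5 by 1.14 and AREG, a ligand of the EGF receptor, by 1.08. Genes not past the threshold were CXCL8 at -0.42, CCL20 at -1.20, TNF at 0.15, CSF3 at 0.11, PTGS2 at -0.49, LCN2 at 0.54, SAA3 at 1.49, ZFP36 at -0.39 and MUC5AC at 0.17.

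In all 748 genes rose and 692 fell, 279 of the 1440 by at least 2-fold, with 3455 at an unadjusted p under 0.05. With the replicate block 1565 rose and 1618 fell, and all 1440 were among them. Replicates 1 and 2 alone gave 2159 genes and replicates 3 and 4 alone 3478; of 13679 genes tested in both, 701 were called in both with the same direction and 88 with opposite directions, where independent lists would share 268 with the same direction. All 1435 of the genes called with all libraries and tested in both sets had the same direction in both, and 561 of them were called in both. The 1435 were called from these same libraries, so their shared direction is not an independent check. Without replicate 2 of PBS at 24 h the count was 835, without replicate 3 of PBS at 24 h 893, without replicate 2 of PBS at 2 h 939 and without replicate 3 of PBS at 2 h 883. A fit of the PBS groups alone gave 532.

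**Figure D5:**
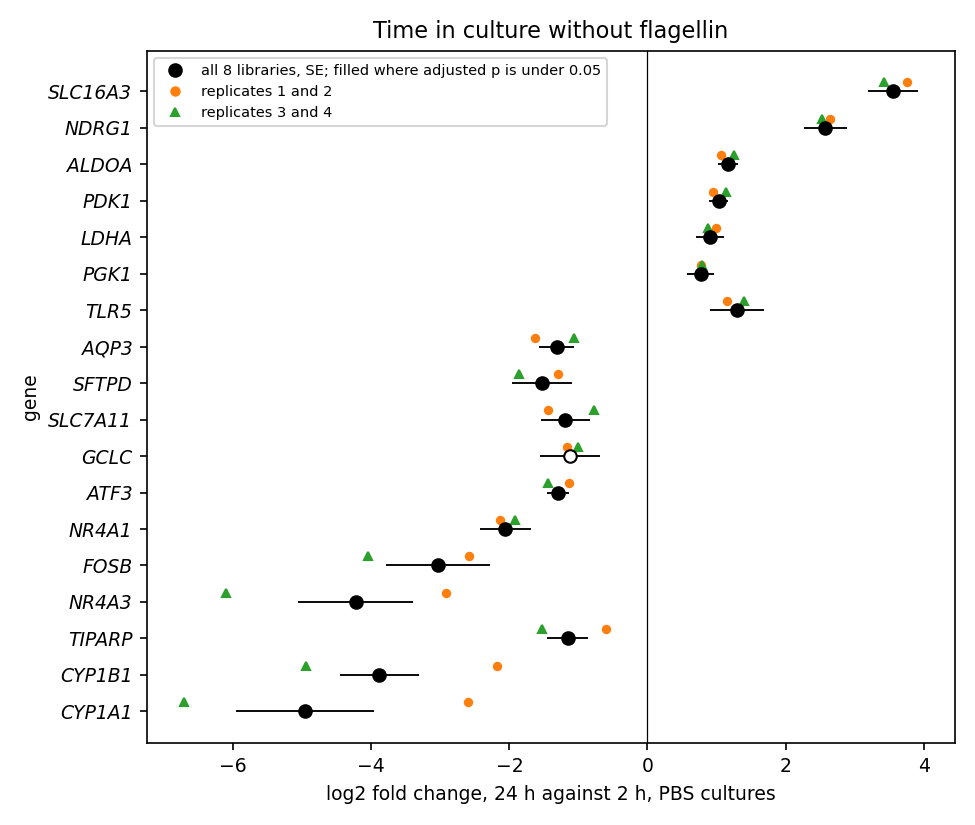
Log2 fold changes with standard errors of 18 named genes, 24 h against 2 h in PBS, with the values of replicates 1 and 2 alone (orange) and 3 and 4 alone (green); the open symbol, GCLC, did not pass the threshold. SLC16A3 is at 3.55 and CYP1A1 at -4.96, with 3.76 and -2.60 in replicates 1 and 2 and 3.42 and -6.72 in replicates 3 and 4.

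Whether the effect of flagellin differed between 2 h and 24 h was tested as an interaction, and 6 genes passed, all with a smaller effect at 24 h. CD83 differed by -3.14 (SE 0.399, adjusted p = 0.000601), IRF1 by -2.82 (SE 0.442, adjusted p = 0.00801), NFKBID by -2.70 (adjusted p = 0.00287) and NFKBIE by -1.73 (adjusted p = 0.000567). SPATA2, an adaptor of the deubiquitinase CYLD, differed by -1.45 (adjusted p = 0.0245) and ZNF263 also passed. The NF-kB feedback genes changed as a list, with a median of -0.77 (adjusted p = 0.0019 with an estimated correlation), 2 of 22 members called over all genes and 7 adjusted over the list alone. CXCL8 differed by -2.68 and did not pass. With the replicate block 27 genes passed, among them RND1 at -4.40 (adjusted p = 2.21e-05), CXCL2 at -4.25 (adjusted p = 0.00168) and LIF, a cytokine of the interleukin 6 family, at -3.67 (adjusted p = 0.000921). The chemokines, cytokines and TLR5 signalling components then passed as lists (adjusted p = 0.00702, 0.000865 and 0.00789 with an estimated correlation, and 0.321, 0.187 and 0.0539 without the block). There were 235 genes at an unadjusted p under 0.05, DESeq2 gave 11, replicates 1 and 2 alone 4 and replicates 3 and 4 alone 74.

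For SB203580 the interaction with time gave 0 genes by edgeR, 0 with the replicate block, 0 with a term for the set at each time and 0 by DESeq2. At an unadjusted p under 0.05 there were 113 (0.797% of those tested), 366 (2.58%), 652 (4.6%) and 183 (0.939%). The lower levels of FOS, IL1A and TNFAIP3 with SB203580 at 2 h and the higher levels of CYP1A1, CYP1B1 and MAP2K6 at 24 h were therefore not shown to differ between the times. Of 34 lists 0 passed with an estimated correlation, the NF-kB feedback genes having a median of 0.50 (adjusted p = 0.246 with an estimated correlation), and with the replicate block the cytokines passed (0.0474, against 0.503 without it). Replicates 1 and 2 alone gave 0 genes (494 at an unadjusted p under 0.05) and replicates 3 and 4 alone 1.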

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

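The tests of sequencing depth and of the SB203580 libraries on the difference between the sets, the test without 5 libraries on the genes lowered by SB203580, all tests on CYP1A1, CYP1B1 and MAP2K6, and every fit with a term for the set were chosen after the results were seen.

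The effect of flagellin differed between 2 h and 24 h in 6 genes by a test of the difference itself: CD83 (-3.14), IRF1 (-2.82), NFKBID (-2.70), NFKBIE (-1.73), SPATA2 (-1.45) and ZNF263 (-1.25). The change with time in PBS differed between replicates 1 and 2 and replicates 3 and 4 in 1317 genes. Tests of the same kind found NFKB1, a subunit of NF-kB, with a flagellin effect at 2 h of 0.44 in replicates 1 and 2 and 1.60 in replicates 3 and 4, a difference of 1.15 (adjusted p = 0.00189), and for SB203580 plus flagellin against PBS 0.13 and 1.13, a difference of 0.98 (adjusted p = 0.0137). MAP2K6 differed by 2.32 in the latter comparison (-0.18 and 2.16, adjusted p = 0.0137), and the unnamed gene ENSSSCG00000006525 by 1.42 for SB203580 plus flagellin against flagellin at 24 h (-1.11 and 0.30, adjusted p = 0.0311).

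The first pattern is that the difference between the sets of replicates itself changed between 2 h and 24 h, in 4960 genes over all treatments. Counting error at the depth used is argued against by 125 such genes with a mean log2 CPM of at least 5 and a 2-fold difference, and the 5 libraries low in secretory markers by 5052 genes found without them. Different animals or cultures at the 2 times may be the source: 98.6% of the genes found in PBS had the same sign in the SB203580 libraries, which cannot be told apart from a true difference in the course of time, as the labels name no animal. A biological difference between the animals of the 2 sets, such as sex, also stays open and was not tested.

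The second pattern is that genes raised by flagellin at 2 h, such as IL1A, TNFAIP3 and IRF1, were lower with SB203580. The sharing of the flagellin libraries is argued against as the whole source, because with those libraries split the least negative of 4 medians was -0.496 (-0.314 with the term for the set). These medians cover the genes called raised in each split, 10 to 17 genes (86 to 119 with the term for the set), not all 42. The 5 libraries low in secretory markers are argued against by a median of -0.483 without them. An action of SB203580 that needs no flagellin stays open, because cultures with SB203580 alone were not analysed here. Of 37 genes lowered in the fit with a term for the set, 20 were raised by flagellin, and none of these was called lower than PBS. Another 8 fell against PBS (RBM18, SERTAD3, COQ10B, ZFP36L1, FOS, DUSP1, TOB1 and KBTBD2) and 9 did neither. As the 8 were not called raised by flagellin, they are not genes of this pattern.

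The third pattern is the higher level of CYP1A1, CYP1B1 and MAP2K6 with SB203580 at 24 h. Chance values of the flagellin libraries are argued against by the comparison with PBS, where the smallest of the 3 differences was 2.27, for CYP1B1. Chance values of the SB203580 libraries stay open, as both comparisons use the same ones and the genes were picked from them. The 5 libraries low in secretory markers are argued against as the whole source by a smallest difference of 1.62 without them, again for CYP1B1. It was 1.95 (SE 0.251, adjusted p = 0.00408) before and 1.62 (SE 0.364, adjusted p = 0.176) after. MAP2K6 was then at 1.99 (SE 0.363, adjusted p = 0.085). CYP1A1 was at 2.46 (SE 0.716, adjusted p = 0.274), so the argument is weaker for it. All 3 calls ended, with 2 of the 4 SB203580 libraries left. Whether targets of the aryl hydrocarbon receptor moved as a class stays open, as the other tested members had a median of 0.0187 and went both ways (AHRR 0.95, TIPARP 0.02, ALDH3A1 -1.07). No biological explanation was tested.

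A single library lay far from the other 3 of its group in 21 of 336 groups tested, where chance gives about 1 in 20 groups (16.8). Flagellin at 24 h had replicate 1 with 16436 detected genes (others 15903 to 15925), LCN2 at 146 CPM (13.7 to 23.9), SAA3 at 88.4 (22.2 to 33.5) and MUC5AC at 1310 (219 to 333). Replicate 2 of the same group had a TMM factor of 0.836 (1.03 to 1.05), PTGS2 at 284 CPM (73.6 to 77.9), eicosanoid enzymes at 3.90 log2 CPM (3.37 to 3.39) and the p38 and stress kinase pathway at 4.99 (4.69 to 4.71). PBS at 2 h had replicate 1 with LCN2 at 187 CPM (29.9 to 52.7), SAA3 at 37.6 (5.44 to 8.71), MUC5AC at 2507 (525 to 847) and TNF at 3.68 (0 to 0.469), and replicate 2 with TLR5 at 0.375 (0.875 to 0.958) and basal cell markers at 6.63 log2 CPM (6.27 to 6.33). In flagellin at 2 h, replicate 3 had NF-kB feedback genes at 6.23 (others at most 6.03) and apoptosis and p53 targets at 6.14 (6.05 to 6.05), and replicate 4 had ion and fluid transport at 5.93 (6.15 to 6.18). In SB203580 plus flagellin at 2 h, replicate 1 had TLR5 signalling components at 4.82 (4.71 to 4.73) and eicosanoid enzymes at 3.84 (3.41 to 3.46), and replicate 2 had CSF3 at 1.16 CPM (0.112 to 0.172); at 24 h replicate 2 had IL6 at 0.452 CPM (0.108 to 0.112).

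Other splits of the same libraries were fitted for each count. For time in culture the real split gave 1440 genes and the other 34 of 35 splits at most 0. Many of these splits mix the sets of replicates unevenly, which the real one does not, so they are not a like reference. The splits that are alike, 8 that part all pairs or 18 that balance the sets, are too few for a share under 0.05. Chance is therefore not excluded by the splits. With the term for the set at each time the real split gave 4700 and the highest other of the 18 balanced splits 1075. For the interaction of flagellin with time, 6 genes against at most 1023, 2 of 100 splits gave as many. Only 2 of the 100 part as many pairs of numbers as the real one, too few for a share under 0.05. Whether the split with 1023 follows the sets of replicates was not tested. Nor can chance be excluded without a block for flagellin at 2 h (46 genes, highest other 1135), SB203580 at 2 h (1, highest other 1883), or SB203580 plus flagellin against PBS at 2 h (26, highest other 2003) and 24 h (1, highest other 4710), where 2 of 35 splits each gave as many. In each of these the larger split parted replicates 1 and 2 from replicates 3 and 4, which points to a structure of the samples; with the replicate block the counts were 151, 5, 114 and 9 against at most 0. Among the 8 splits that part all 4 pairs of numbers, as the real one does, the highest other count was 0 in every comparison of 2 groups, but 8 are too few for a share under 0.05; the larger counts came from splits that part fewer pairs. For results of 0 genes by edgeR any split gives a count as large, so splits say nothing of chance: flagellin at 24 h (35 of 35, highest other 5766), SB203580 at 24 h (35 of 35, 6323), the interaction of SB203580 with time (100 of 100, 5705), and genes raised by flagellin and lowered by SB203580 at 2 h (100 of 100, 0) and 24 h (100 of 100, 707). At an unadjusted p under 0.05 the first 3 of these had 112, 405 and 113 genes, and DESeq2 called 0 to 1.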

How the results depend on the processing

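The tests with a term for the set of replicates, on each set alone and without the 5 libraries low in secretory markers were chosen after the data were seen. In what follows counts are in the order flagellin at 2 h, SB203580 at 2 h and SB203580 plus flagellin against PBS at 2 h, unless named. RLE scaling and no count filter moved no count by over 1.5 times, and no count, named gene call or list call reversed. Lists past camera at the preset correlation alone did turn: of 99 such tests, 10 turned in replicates 3 and 4 alone (4 of them past the threshold) and 11 without the 5 libraries (2 past). The ciliated cell markers for SB203580 at 24 h turned upward in replicates 3 and 4 alone at the preset correlation (adjusted p = 3.93e-07), without passing both forms of camera (adjusted p = 0.36 with an estimated correlation). Of 94 calls of named genes 94 were kept with the replicate block, with the term for the set at each time and by DESeq2, 93 with RLE, 84 with no filter, 53 in the groups compared alone and 75 without the 5 libraries. Replicates 1 and 2 alone kept 58 and replicates 3 and 4 alone 82. With each library left out in turn, a named gene call was kept 542 times and lost 250 times. Of 6 calls of lists 6 were kept with the replicate block, and leaving out 1 library lost a call 11 times in all, named beside the results. The TLR5 signalling components at 2 h were lost with RLE (adjusted p = 0.0578 with an estimated correlation), no filter (0.0729), the term for the set at each time (0.105), the groups compared alone (0.0786) and replicates 1 and 2 alone (0.457). The cytokines were lost with no filter for flagellin (0.0798) and for SB203580 plus flagellin against PBS at 2 h (0.546), and the NF-kB feedback genes for flagellin by time in replicates 1 and 2 alone (0.066). With the replicate block the counts were 151, 5 and 114, with 9 for SB203580 plus flagellin against PBS at 24 h, 3183 for time, 27 for flagellin by time and 2 for the overlap at 2 h. Apart from these and the lists named beside their results, the block changed no other call. The term for the set gave 159, 5 and 114, with 11, 3325, 22 and 3 for the same further results, and the term for the set at each time 318, 53 and 281, with 65, 4700, 38 and 20, and 13 for SB203580 at 24 h.

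DESeq2 gave 102, 13 and 81, with 1 for flagellin and 1 for SB203580 at 24 h, 10 for SB203580 plus flagellin against PBS at 24 h, 11 for flagellin by time and 4 for the overlap. The groups compared alone gave 24, 2 and 6, with 0 against PBS at 24 h by edgeR, 532 for time and 1 for the overlap; fewer libraries estimate the spread there. Replicates 1 and 2 alone gave 20, 0 and 14, with 2 for SB203580 at 24 h and 2 against PBS at 24 h. Replicates 3 and 4 alone gave 198, 93 and 183, with 1 and 2 for the same, 3478 for time, 74 for flagellin by time, 1 for SB203580 by time and 32 for the overlap. Without the 5 libraries SB203580 at 2 h had 3, SB203580 plus flagellin against PBS at 24 h 0 and the overlap 1; with the replicate block as well these were 27, 0 and 12, with 178 for flagellin at 2 h, 114 against PBS at 2 h, 3344 for time and 27 for flagellin by time. With the term for the set at each time as well they were 286, 22 and 78, with 671, 573, 5492 and 84, and 2 for flagellin at 24 h, 1 for SB203580 at 24 h and 5 for SB203580 by time. Apart from the loss of libraries, the cause was not tested.

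Leaving out 1 library gave 15 to 42 for flagellin at 2 h, 1 to 2 for SB203580 at 2 h, 10 to 25 and 0 to 2 for SB203580 plus flagellin against PBS at 2 h and 24 h, 835 to 1319 for time and 5 to 8 for flagellin by time. The libraries concerned are, for flagellin at 2 h, PBS 2 (22) and 3 (15) and flagellin 3 (20) and 4 (29); for SB203580 at 2 h, SB203580 3 (2); against PBS at 2 h, PBS 1 (13), 2 (10) and 3 (11) and SB203580 3 (16) and 4 (13); at 24 h, PBS 1 to 4 and SB203580 1 and 2 (0 each) and SB203580 4 (2); for time, PBS at 24 h 2 (835) and 3 (893) and at 2 h 2 (939) and 3 (883). Of the genes given in every comparison that did not pass and had a log2 difference over 0.5 in size, 2 turned sign without 1 library: TNF with SB203580 at 24 h without replicate 1 of SB203580 plus flagellin (-0.88, and -0.64 against PBS), and CSF3 against PBS at 2 h without replicate 2 of it (-0.34). Depth limits genes near the floor of 0.0827 to 0.114 CPM.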

Other observations

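The tests behind the differences between sets below were chosen after the data were seen. The genes below are among the largest by the difference between the sets in the change with time in PBS, of those with a symbol and a mean log2 CPM of at least 5; the differences and adjusted p are for PBS alone, and the levels are over all 3 treatments. TFRC, the transferrin receptor, went from 7.10 ± 0.21 to 5.53 ± 0.45 log2 CPM (SD, n = 6 each) in replicates 1 and 2 and from 6.41 ± 0.18 to 6.16 ± 0.23 in replicates 3 and 4, a difference of 2.02 (adjusted p = 0.00167). F3, tissue factor, went from 10.7 to 11.6 and from 12.1 to 11.6, a difference of -1.60 (adjusted p = 0.00436), and the collagen receptor subunit ITGA2 from 7.18 to 7.99 and from 7.90 to 7.43, a difference of -1.60 (adjusted p = 0.0024). CCN1, a matrix protein, differed by -1.79, the sulfate carrier SLC26A2 by -1.49, the microtubule protein MAP2 by 1.63 and MRPS6, a mitochondrial ribosomal protein, by 1.51. CYP1A1 differed by -4.10 and CYP1B1 by -2.76. In PBS alone 738 genes had a higher and 579 a lower change with time in replicates 3 and 4, and in the SB203580 libraries 636 and 732.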
